A study of Homo sapiens with 26 samples.

How the data were processed

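RNA of human airway epithelial 16HBE cells was sequenced in 26 libraries: 6 of WT cells in normal glucose, 5 of WT cells in high glucose, 6 each of CF cells in normal and in high glucose, and 3 of WT cells in normal glucose labelled as not polarized. Per the labels, 2 Transwells were pooled per sample, 250000 cells were plated per well, messenger RNA was captured with poly-T beads, and reads were aligned with HISAT2 to hg38. The counting tool, the strand setting and the version of the aligner are not given in the sources used here, so counts of overlapping genes on opposite strands may mix. The deposited tables hold raw counts per gene for 58735 genes, and FPKM values that the authors scaled to gene length and library total. Counts were whole numbers, and within a library each FPKM equalled the count over length and total times a constant, which ranged from 0.945 to 1.07 between libraries. The gene identifiers and positions of all 58735 genes matched GENCODE release 29 on GRCh38, and 35380 genes had at least 1 read. Library totals ran from 14658319 to 20413839 counts. No library was left out of the tables.

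Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr by group (minimum count 10, minimum total 15), quasi-likelihood fits with robust dispersion, and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 called. The 23 glucose libraries shared a fit with 4 group means and 19 residual degrees of freedom, which tested 16338 genes. It gave the response to glucose in each line, their difference (interaction) and CF against WT at each glucose level. The WT normal glucose and not polarized libraries had a fit of their own with 16105 genes. CPM are counts scaled to TMM-adjusted library size by edgeR, and errors are SD over libraries or SE of the log2 fold change as named. Overlaps of called genes were set beside the number expected from the product of the shares called. P-values of genes and lists in the text are from these models.

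Members of 33 gene lists (pathways, complexes and cell types, chosen for airway epithelium and glucose) were counted as called over all genes and adjusted over the list alone. Each list with at least 5 tested members was tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison, and again with a correlation estimated from the data. The gene lists, the model, the rule for named genes and the first set of alternatives below were chosen before the data were examined. The rule for named genes took the 5 highest and 5 lowest fold changes among called protein-coding genes with a mean of at least 5 CPM in a group and no overlap between the groups' libraries. It added up to 2 called members of the tight junction, adherens junction, ion transport, glucose-responsive, glycolysis and cytokine lists and up to 3 of other lists called by camera, up to 30 genes, members needing a mean of at least 1 CPM. For the interaction it took the 10 lowest p-values, and CFTR, TXNIP, CLDN4, TJP1, OCLN and CDH1 were always given. Other list members named in the text, such as SLC2A10, FOXJ1, SLC7A11 or the members lying in chromosome blocks, were chosen after their values were seen. Some genes that the rule takes are not reported here.

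Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a stricter filter (CPM of at least 1 in at least 5 libraries, 3 in the not polarized fit), limma-trend on log2 FPKM plus 1 or plus 0.1 (FPKM of at least 0.5 in 3 libraries, or no filter). Others were a surrogate variable from sva 3.50.0, protein-coding genes alone, removal of mitochondrially encoded genes, another set of libraries in the fit, a block for the number in the library name, and each library left out in turn. After the data were seen, a batch term for libraries numbered 1 to 3 against 4 to 6, each of these sets alone, the batch term with an estimated correlation, and CF without its high glucose library 6 were added. The library numbers were not taken as pairs. Across genes, which are not independent, the mean r of residuals of libraries with the same number was 0.24 for glucose in WT, 0.26 in CF, 0.16 and 0.23 between the lines and -0.0046 for the not polarized comparison, against 0.22, 0.24, 0.17, 0.23 and 0.0019 for other libraries of the same set of numbers (1 to 3 or 4 to 6), and in no comparison was every pair above 0.1. Counts of genes were compared with up to 100 other splits of the libraries. Windows of 50 neighbouring genes were scanned for shared differences between the lines against 200 shuffled gene orders, and 5 of 5 planted blocks of 100 genes at 1.5-fold were recovered on simulated data with 0 windows outside them. Shorter blocks and smaller shifts, such as those of several regions reported below, were not planted, so their recovery was not tested.

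The pipeline was tested on simulated data with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold per comparison, and the hypoxia list shifted by 1.3-fold. The simulated genes were drawn independently of each other. No difference between libraries numbered 1 to 3 and 4 to 6 was simulated, so the test covers neither correlated genes nor such a difference. At 1.5-fold it recovered 74.6% of changed genes for glucose in WT, 77.6% in CF, 53.7% for the interaction, 79.1% and 65.7% for the lines in normal and high glucose (16338 genes run each), and 76.1% for the not polarized comparison (16105 genes run). At 2-fold the shares were 98.5%, 94%, 86.6%, 95.5%, 94% and 92.5%, and at 4-fold 100% in all. There were 12, 10, 7, 6, 5 and 9 false calls, and camera called the shifted list in all 6 comparisons (adjusted p of 7.59e-12 or less) and, glycolysis aside as it shares members, 2 other lists in the first and 1 in the second. Figures were drawn with matplotlib 3.10.9. Levels of genes on the sex chromosomes that could serve to infer sex were not used here.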

Results

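Bulk RNA sequencing was performed on 16HBE cells, a line of human bronchial epithelial cells, to ask how raised glucose affects airway epithelial cells that carry wild-type CFTR (WT, 16HBE14o-) or a CFTR mutation that causes cystic fibrosis (CF, 16HBEge, a gene-edited derivative). The genotype of the CF cells is given as DeltaF508 CFTR and that of the WT cells as WT CFTR. CFTR is the chloride and bicarbonate channel of the apical membrane. Cells grown on Transwells were kept for 7 days in normal (5.5 mM) or high (17.5 mM) glucose. There were 6 libraries of WT cells in normal glucose, 5 of WT cells in high glucose, 6 of CF cells in normal glucose and 6 of CF cells in high glucose. A further 3 libraries came from WT cells in normal glucose that the labels call not polarized. The 26 libraries held between 14658319 and 20413839 counts each. The labels do not state whether libraries of a group came from separate cultures, so the p-values measure the spread between these samples and no more.

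CFTR (ENSG00000001626, GRCh38 chromosome 7, 117465784 to 117715971) was expressed in all 26 libraries, between 583 and 867 CPM. Its mean was 693 ± 17.5 CPM (SD, n = 6) in WT and 754 ± 73.2 CPM (n = 6) in CF cells in normal glucose. In high glucose it was 658 ± 40.5 CPM (n = 5) in WT and 646 ± 63.5 CPM (n = 6) in CF cells. Counts per gene do not show the sequence that a line carries, so they do not test the genotype. The lines separated on the first principal component of the 23 glucose libraries, which held 36.7% of the variance. The second component (16.6%) separated libraries numbered 1 to 3 from those numbered 4 to 6 in each of the 4 groups. After the group means were removed, the first component of what remained (29.6% of its variance) separated the same sets. The share of counts on ribosomal protein genes was lower in the libraries numbered 4 to 6 in each of the 4 groups, for example a mean of 3.35 ± 0.0719% (SD, n = 3) against 4.35 ± 0.221% (n = 3) in CF cells in high glucose. Results are therefore given beside values from a fit with a batch term for library number (1 to 3 or 4 to 6) and from each set of numbers alone.

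**Figure D1:**
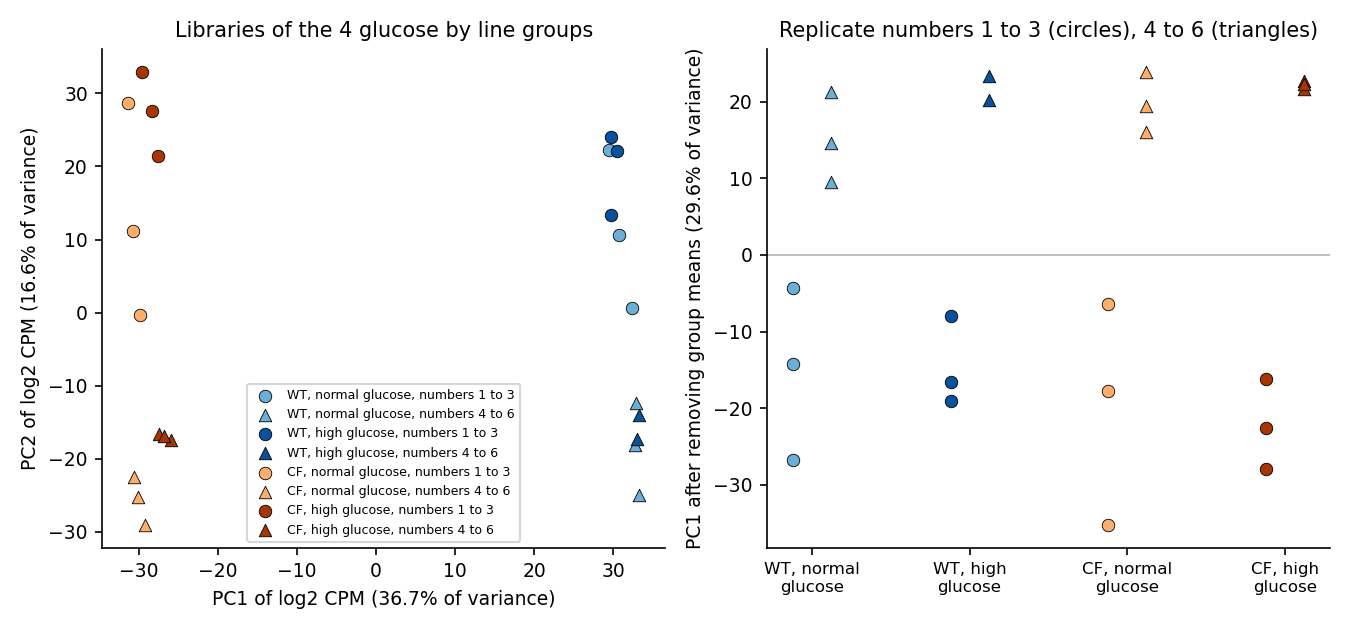
Principal components of log2 CPM for the 23 glucose libraries (left, both axes unitless scores) and the first component after removing group means (right, score per library). Colours mark the 4 groups, circles the libraries numbered 1 to 3 and triangles those numbered 4 to 6; the lines part along the first axis (36.7% of variance), and circles and triangles do not overlap on the right.

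The first comparison asked which genes responded to high glucose in WT cells. TXNIP, a glucose-induced inhibitor of thioredoxin and of glucose uptake, rose 2.29-fold, from 291 ± 51.7 CPM (SD, n = 6) to 667 ± 48.5 CPM (n = 5) (log2 fold change 1.20 ± 0.16 SE, adjusted p = 0.000156; ENSG00000265972, GRCh38 chromosome 1, 145992435 to 145996600). Its relative ARRDC4, also an arrestin that lowers glucose uptake, rose 2.19-fold (log2 1.13 ± 0.14; ENSG00000140450, chromosome 15, 97960698 to 97973838), and the transcription factor KLF10 rose 1.53-fold (log2 0.61 ± 0.07). HK2, a hexokinase, which phosphorylates glucose, fell from 386 ± 62.2 CPM (n = 6) to 205 ± 28.2 CPM (n = 5) (log2 -0.91 ± 0.15, adjusted p = 0.000811; ENSG00000159399, chromosome 2, 74833981 to 74893359). The glucose transporters SLC2A3 (log2 -0.45) and SLC2A1 (log2 -0.38) fell as well.

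Beyond these, the called protein-coding genes with a mean of at least 5 CPM and no overlap between libraries that rose most in WT cells included the kinase SGK1 (2.18-fold), which regulates sodium transport, and the vitamin D hydroxylase CYP24A1 (2.00-fold). VIT (log2 -1.11), the BMP antagonist NOG (log2 -0.96), RNF223 (log2 -0.96), PAG1 (log2 -0.94) and the Notch ligand DLL1 (log2 -0.92) fell most by the same rule. PAG1 was not called without WT high glucose 4 (adjusted p = 0.0514) or on FPKM (0.0841 with 1 added, 0.0534 with 0.1 added and 0.12 without a filter). Among 32 tested members of the cytokine and NF-kB list, 5 rose, none fell and 27 were not called, with 11 higher and 1 lower when adjusted over the list alone. The chemokine CCL5 rose 1.63-fold and the mitochondrial superoxide dismutase SOD2 1.46-fold. The list was higher by camera (adjusted p = 3.79e-07, but adjusted p = 0.17 with an estimated correlation). Of 34 interferon response genes, 5 rose and 29 were not called (9 higher adjusted over the list alone), among them the RNA helicases DDX60 (log2 0.53) and DDX58 (log2 0.41) and the nuclease ISG20 (log2 0.38). The camera adjusted p was 1.68e-06, and the adjusted p = 0.175 with an estimated correlation. DDX58 was not called without WT high glucose 3 (adjusted p = 0.0719), WT normal glucose 3 (0.0505) or WT normal glucose 6 (0.0539). On FPKM without a filter neither DDX58 (0.0801) nor ISG20 (0.0588) was called.

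Of 22 hypoxia genes, 5 fell in WT cells, 0 rose and 17 were not called (11 lower adjusted over the list alone). ADM, the vasodilator peptide adrenomedullin, fell (log2 -0.75), as did PDK1, a kinase that inhibits pyruvate dehydrogenase (log2 -0.32). The list was lower with a camera adjusted p of 6.76e-08 and an adjusted p = 0.132 with an estimated correlation. Of 28 glycolysis and glucose transport genes, 5 fell and 1, the transporter SLC2A10, rose (7 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.00044, adjusted p = 0.175 with an estimated correlation). In the wound healing and protease list 4 of 24 rose and 1 fell (8 and 1 adjusted over the list alone), with the plasminogen activator PLAT at 1.53-fold and the sheddase ADAM17 at 1.19-fold (camera adjusted p = 0.000219, adjusted p = 0.175 with an estimated correlation). In the cytosolic heat shock list 2 of 18 rose, the chaperone HSPH1 at 1.26-fold and the cochaperone AHSA1 at 1.17-fold (4 adjusted over the list alone, camera adjusted p = 0.000219, adjusted p = 0.175 with an estimated correlation). Smaller camera calls were those of the polyol and hexosamine (2 of 19 rose, 2 adjusted over the list alone, adjusted p = 0.0117), innate defence and mucus (4 of 17 rose, 1 fell; 6 and 1 adjusted over the list alone, adjusted p = 0.00703) and cell cycle lists (1 of 35 fell, 1 adjusted over the list alone, adjusted p = 0.00703). With an estimated correlation these had adjusted p = 0.0759, 0.0759 and 0.491, and the innate defence list had 0.0578 with a block for the library number. AHSA1 was not called without WT high glucose 2, 3, 4 or 5 or WT normal glucose 1, 2, 3, 4 or 6 (adjusted p from 0.0525 to 0.12), without a low-count filter (0.184), in a fit of the WT libraries alone (0.0556) or on FPKM without a filter (0.072).

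Of 31 tight junction genes, CLDN1, a barrier-forming claudin, rose 1.25-fold in WT cells, from 820 ± 23.3 CPM (n = 6) to 1027 ± 65.9 CPM (n = 5). LSR of tricellular junctions fell (log2 -0.24) and 29 were not called (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.926). Of 26 adherens junction and desmosome genes only the desmosomal plaque gene PKP2 was called (log2 -0.20; 1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.183). TJP1 (log2 -0.08), OCLN (log2 -0.06), CLDN4 (log2 -0.06) and CDH1 (log2 -0.18) did not pass the test, nor did CFTR (log2 -0.07, adjusted p = 0.702). In the ion and fluid transport list 4 of 27 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.14), with ATP1B1, the sodium pump beta subunit, at 1.25-fold and the anion exchanger SLC4A2 at log2 -0.32. PKP2 was not called without WT high glucose 1, 2, 3 or 5 or WT normal glucose 3, 4 or 5 (adjusted p from 0.0517 to 0.108), without a low-count filter (0.21) or in a fit of the WT libraries alone (0.0913). LSR was not called without WT high glucose 2 (0.052) or 5 (0.0639) or without a low-count filter (0.0535). Of 20 glucose-responsive genes 3 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0514).

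In all, 482 of 16338 tested genes were called in WT cells (244 higher and 238 lower in high glucose; 22 by at least 2-fold), and 2474 had an unadjusted p under 0.05. Across genes, which are not independent, length and GC content held 5.84% of the variance of the log2 fold changes (r with GC content -0.189). A batch term for library number gave 1418 genes, which included the 482, while libraries numbered 1 to 3 alone gave 424 and those numbered 4 to 6 alone gave 823. DESeq2 gave 809 genes, and leaving out WT high glucose 3 or WT normal glucose 6 gave 281 or 309. In libraries numbered 1 to 3 alone ADM (adjusted p = 0.0561), AHSA1 (0.17), ISG20 (0.18), PDK1 (0.138) and PKP2 (0.125) and the cell cycle (0.112) and innate defence lists (0.338) were not called. In those numbered 4 to 6 alone LSR (0.0935) and PKP2 (0.172) were not.

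**Figure D2:**
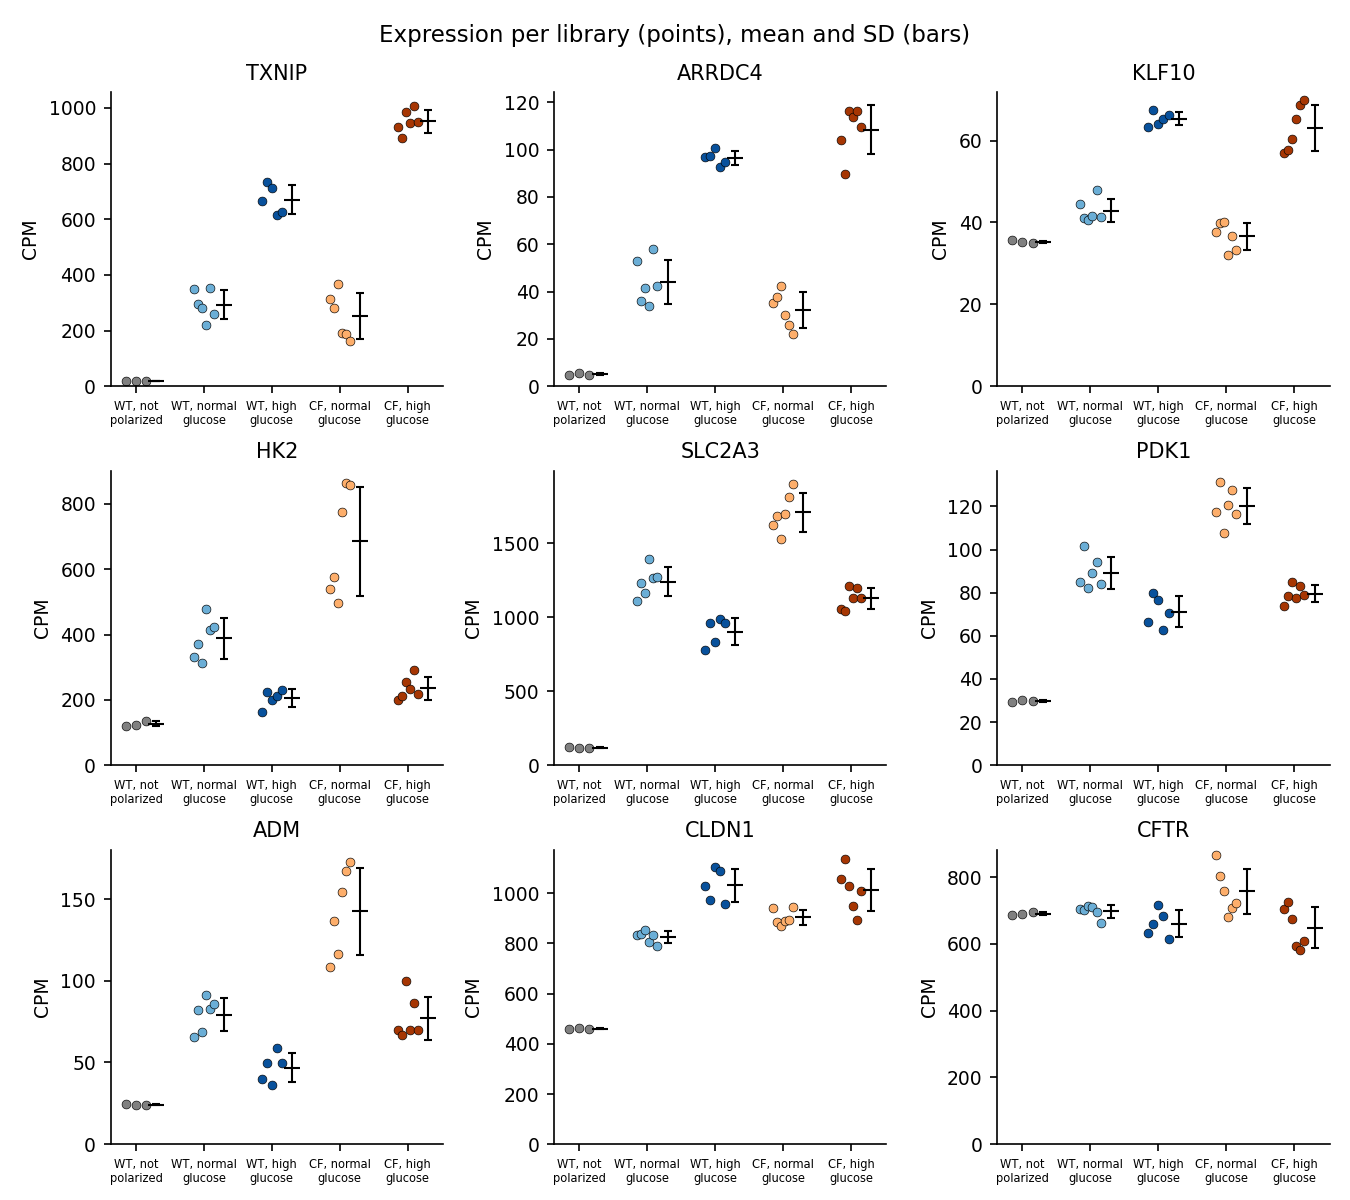
CPM of 9 genes in each of the 26 libraries (points, in order of library number within a group), with group mean and SD (bars); the y axes are linear and start at 0. TXNIP, ARRDC4 and KLF10 were higher and HK2, SLC2A3, PDK1 and ADM lower in high than in normal glucose in both lines; CFTR lay between 583 and 867 CPM.

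The same question was asked of CF cells. TXNIP rose 3.78-fold, from 251 ± 84.7 CPM (SD, n = 6) to 947 ± 40.0 CPM (n = 6) (log2 1.92 ± 0.16 SE, adjusted p = 9.07e-08), ARRDC4 rose 3.35-fold (log2 1.75 ± 0.14) and KLF10 1.72-fold. HK2 fell from 680 ± 160 CPM to 234 ± 33.7 CPM (n = 6 each; log2 -1.54 ± 0.14, adjusted p = 1.98e-07). PLIN2, which coats lipid droplets, fell from 85.4 ± 15.3 to 38.1 ± 3.43 CPM (n = 6 each; log2 -1.16 ± 0.10; ENSG00000147872, chromosome 9, 19108375 to 19149290). Other named genes that fell were PAG1 (log2 -1.37), the Wnt receptor ROR2 (log2 -1.17) and NOG (log2 -1.03), and others that rose were FAM78A (2.14-fold), ZNF503 (1.89-fold) and the growth factor BMP5 (1.84-fold).

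The hypoxia list was the list with the most calls in CF cells: 17 of 22 members fell, 0 rose and 5 were not called (18 lower adjusted over the list alone). ADM fell (log2 -0.89), as did KDM3A, a histone demethylase (log2 -0.61), PDK1 (log2 -0.59) and EGLN1, an oxygen sensor that marks HIF for degradation (log2 -0.54). The camera adjusted p was 3.53e-28, and the call held with an estimated correlation (adjusted p = 0.00148). Of 28 glycolysis and glucose transport genes 9 fell and 1 rose (14 and 2 adjusted over the list alone), including SLC2A3 (log2 -0.60) and SLC2A1 (log2 -0.54) among the falls and SLC2A10 (log2 0.59) as the rise (camera adjusted p = 9.26e-05, adjusted p = 0.195 with an estimated correlation). Of 20 glucose-responsive genes 3 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.0579), PFKFB4 and PFKFB3 being among those that fell.

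Of 17 innate defence and mucus genes 5 rose and 1 fell in CF cells (6 and 1 adjusted over the list alone), and this call held with an estimated correlation (camera adjusted p = 0.00392, adjusted p = 0.0212 with an estimated correlation). The antiprotease PI3 rose 1.70-fold, complement factor CFB 1.57-fold and the acute phase gene SAA2 1.43-fold, whereas the complement gene C3 fell (log2 -0.32). SAA2 is nearly identical in sequence to SAA1, so reads of the pair are hard to assign. Of 18 cytosolic heat shock genes 5 rose and 1, HSF1, fell (8 and 1 adjusted over the list alone), with the near-identical HSPA1A and HSPA1B at 1.44-fold and 1.33-fold and HSPB1 at 1.26-fold (camera adjusted p = 9.26e-05, adjusted p = 0.195 with an estimated correlation). Of 25 cholesterol synthesis genes 1, the squalene synthase FDFT1, rose (1.32-fold; 1 adjusted over the list alone, camera adjusted p = 0.00414, adjusted p = 0.582 with an estimated correlation). Of 34 interferon response genes 3 rose, MX1 among them at 1.18-fold (4 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.582 with an estimated correlation). Of 29 actin and myosin genes 4 fell (5 adjusted over the list alone, camera adjusted p = 0.0412, adjusted p = 0.582 with an estimated correlation). The interferon list was not called without CF high glucose 1 (adjusted p = 0.0505), 2 (0.0899) or 3 (0.0863), nor MX1 without CF high glucose 2 (0.0712) or 3 (0.0503) or CF normal glucose 1 (0.0554) or without a low-count filter (0.0584). The actin and myosin list was not called without CF high glucose 4 (0.0718), 5 (0.0805) or 6 (0.171) or CF normal glucose 5 (0.0527) or 6 (0.0801). The cytokine and NF-kB list, 2 of 32 higher and 4 lower (3 and 8 adjusted over the list alone), was not called (camera adjusted p = 0.404); the cytokine LIF fell (log2 -0.41) and the macrophage growth factor CSF1 rose (log2 0.49).

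Among 31 tight junction genes in CF cells 3 fell and 1 rose (3 and 2 adjusted over the list alone, camera adjusted p = 0.468). The strand protein OCLN fell (log2 -0.26), from 145 ± 7.14 to 121 ± 7.85 CPM (n = 6 each), and so did the polarity gene PARD6B (log2 -0.38). Of 26 adherens junction and desmosome genes 4 fell and 1 rose (6 and 3 adjusted over the list alone, camera adjusted p = 0.176), with PKP2 at log2 -0.36 and NECTIN1 at log2 0.53. TJP1 (log2 -0.10), CLDN4 (log2 0.05) and CDH1 (log2 -0.20, adjusted p = 0.0828) did not pass. In the ion and fluid transport list 6 of 27 rose and 5 fell (7 each adjusted over the list alone, camera adjusted p = 0.404), with ATP1B1 at 1.35-fold and SCNN1A, the alpha subunit of the epithelial sodium channel, at 1.28-fold. CFTR fell (log2 -0.22, 0.857-fold, adjusted p = 0.0348). That call was lost without CF high glucose 4 (adjusted p = 0.0608), 5 (0.0632) or 6 (0.0802), without CF normal glucose 1 (0.0658) or 2 (0.0798), without a low-count filter (0.0703) in a fit of the CF libraries alone (0.0813) and on FPKM without a filter (0.0539).

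In all, 1374 of 16338 genes were called in CF cells (698 higher and 676 lower; 48 by at least 2-fold). A batch term gave 2811 genes, which included the 1374. Libraries numbered 1 to 3 alone gave 1349 (705 higher and 644 lower) and those numbered 4 to 6 alone gave 2328 (924 higher and 1404 lower). In libraries numbered 1 to 3 alone OCLN (adjusted p = 0.0518) and the actin and myosin list (0.844, in the other direction) were not called, and in those numbered 4 to 6 alone MX1 (0.179) and the interferon list (0.291) were not.

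Whether the response differed between the lines was tested as an interaction. Genes called in both lines numbered 254, of which 124 rose in both, 128 fell in both and 2 went opposite ways, against 10.4 and 9.85 shared rises and falls by chance. Across all 16338 genes, which are not independent replicates, the log2 fold changes of the lines had r = 0.409, or 0.393 with the batch term, 0.336 in libraries numbered 1 to 3 and 0.188 in those numbered 4 to 6. Of the 1602 genes called in either line, 91.3% had the same sign in both.

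The difference itself was called for 6 genes. PLIN2 fell in CF cells (log2 -1.16) and was not called in WT cells (log2 -0.37), a difference of log2 fold changes of -0.79 ± 0.14 SE (adjusted p = 0.0309). CTGF, a matricellular growth factor (ENSG00000118523, chromosome 6, 131948176 to 131951373), rose in WT (log2 0.28) and fell in CF cells (log2 -0.35), a difference of -0.63 ± 0.10 (adjusted p = 0.0176). The histone deacetylase HDAC9 (difference -0.59 ± 0.10) and the focal adhesion gene FHL2 (difference -0.55 ± 0.09) fell in CF cells (log2 -0.76 and -0.35) and were not called in WT cells (log2 -0.17 and 0.20). APCDD1, a Wnt inhibitor (difference 0.47 ± 0.08), and the membrane metalloproteinase MMP15 (difference 0.37 ± 0.07) rose in CF cells (log2 0.44 and 0.42) and were not called in WT cells (log2 -0.03 and 0.05). FAM78A (adjusted p = 0.0943), ESPN (difference 0.63), ROR2 (difference -0.57) and DUSP5 (difference -0.53) did not pass, and nor did TXNIP (difference 0.72 ± 0.23, adjusted p = 0.364), OCLN (difference -0.20, adjusted p = 0.447) or CFTR (difference -0.15, adjusted p = 0.879). As lists, hypoxia (camera adjusted p = 1.35e-10), cytokine and NF-kB (7.01e-10) and wound healing and protease (4.99e-06) were lower in CF than in WT in their response. Each of the 3 had an adjusted p = 0.124 by camera with an estimated correlation, and 0.28 with the batch term added. No member of the 3 lists was called over all genes. When adjusted over the list alone, 6 hypoxia members were lower, ERO1A (-0.46) and INSIG2 (-0.59) among them, 8 cytokine members were lower, CXCL1 (-0.73) and SOD2 (-0.42) among them, and 3 wound healing members were lower, such as HBEGF (-0.60) and MET (-0.26), and 1 higher.

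The interaction had 1109 genes at an unadjusted p under 0.05. Length and GC content held 5.51% of the variance of its log2 differences across genes (r with GC content 0.221). DESeq2 called 67 genes, which included the 6, and limma on FPKM called 4. The batch term gave 146, libraries numbered 1 to 3 alone 1 and those numbered 4 to 6 alone 387. The count was 0 without WT high glucose 2 or WT high glucose 3, 10 without CF normal glucose 1, 13 without CF high glucose 3 and 19 without CF normal glucose 3. It was 3 without CF high glucose 2, CF high glucose 5, CF normal glucose 4, 5 or 6 or WT normal glucose 3. CTGF, HDAC9 and FHL2 were lost without WT high glucose 2 (adjusted p = 0.0597) or 3 (0.0528), APCDD1 without the 8 libraries that left 0 or 3 genes (0.0506 to 0.0597), and PLIN2 (0.0528 to 0.0789) and MMP15 (0.0603 to 0.102) without any of 14. The 14 for PLIN2 were CF high glucose 2, 4, 5 and 6, WT high glucose 2 to 5, CF normal glucose 4 to 6 and WT normal glucose 1 to 3. Those for MMP15 were CF high glucose 1, 2, 4 and 5, WT high glucose 2, 3 and 5, CF normal glucose 2, 4, 5 and 6 and WT normal glucose 2, 3 and 5. In libraries numbered 1 to 3 alone, APCDD1, CTGF, FHL2, HDAC9, MMP15 and PLIN2 (adjusted p from 0.0606 to 0.321) and the cytokine (0.124) and wound healing lists (0.304) were not called, and in those numbered 4 to 6 alone MMP15 was not (0.0743). On FPKM, HDAC9 (0.0559 to 0.127), PLIN2 (0.0525 to 0.136) and, without a filter, FHL2 (0.0608) were not called, and without a low-count filter MMP15 (0.21) and APCDD1 (0.056) were not.

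**Figure D3:**
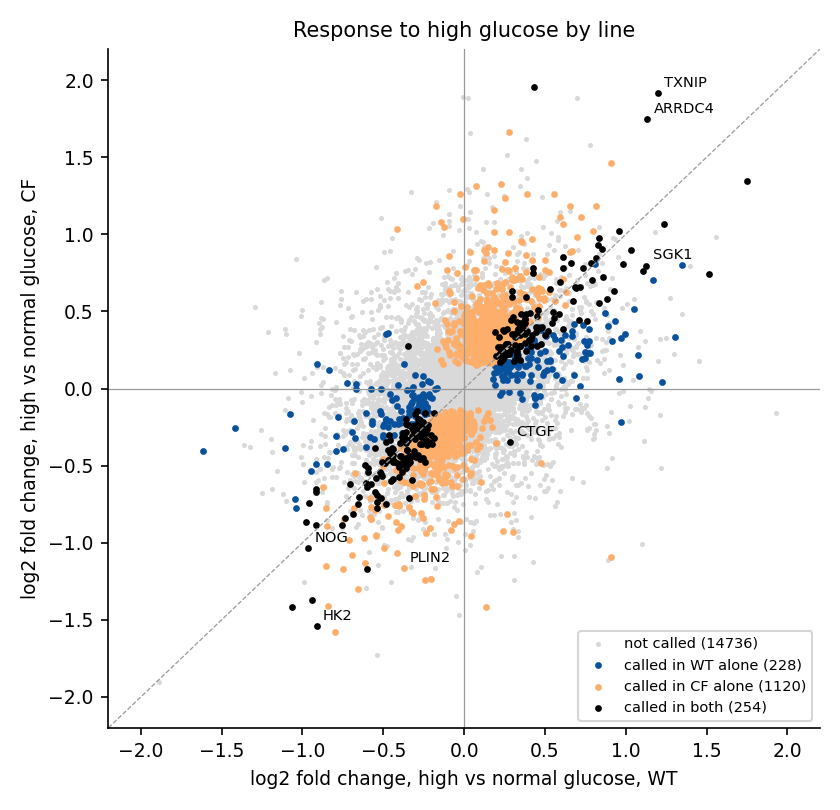
Log2 fold change (high over normal glucose) of each gene in WT (x) and CF cells (y), coloured by the line in which it was called; the dashed line marks equal change, and 7 genes lie outside the axes. Of the 254 genes called in both lines all but 2 changed in the same direction in both.

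**Figure D4:**
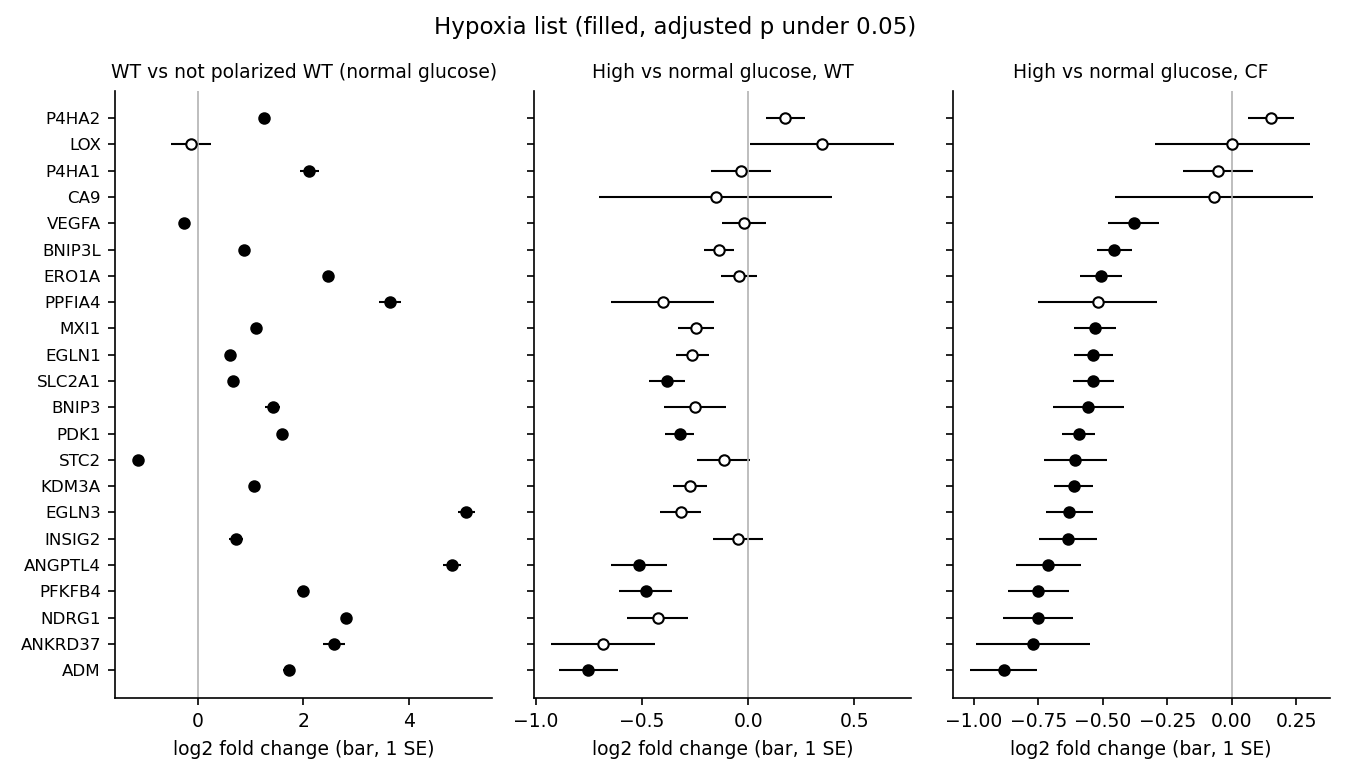
Log2 fold change and SE of the hypoxia list members in WT cells in normal glucose over not polarized WT cells (left) and in high over normal glucose in WT (middle) and CF cells (right); filled points had an adjusted p under 0.05, and the x axes differ in range. Of 22 members 17 fell in CF and 5 in WT cells in high glucose, while 18 of 21 were higher in WT cells in normal glucose than in not polarized cells.

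The lines themselves were compared in each glucose level. Each line is represented by a clone or population of its own, so a difference between CF and WT cells cannot be assigned to CFTR. In normal glucose, MAN1A1, a mannosidase of N-glycan processing, was 130-fold higher in CF cells (11.7 ± 1.04 against 0.08 ± 0.11 CPM, n = 6 each; log2 7.03 ± 0.33 SE; ENSG00000111885, chromosome 6, 119177209 to 119349761). The phosphatase PTPRG was 26.3-fold, DAAM2 19.4-fold, the prostaglandin synthase PTGS2 19.3-fold and PKHD1 8.34-fold higher. TSPYL5 had no count in any CF library. Taking 3 counts over the group as the floor it was at least 276-fold lower in normal and 304-fold lower in high glucose, while the counting interval of the ratio reaches down to 224 and 247. Both cover counting error only. The pluripotency-associated zinc finger gene ZFP42 (log2 -8.55), ZFP28 (log2 -6.62), TCIM (log2 -6.59) and PPP2R2B (log2 -6.44) were also lower in CF cells. PPP2R2B was near the floor in CF normal glucose, at 0.198 CPM in library 1 and a mean of 0.026 CPM in the others, so its ratio is imprecise. In high glucose, MAN1A1 was 107-fold higher, PTPRG 28.0-fold and PTGS2 21.1-fold. The MAN1A1 ratio is imprecise too, as WT high glucose had 0.351 CPM in library 1 and a mean of 0.029 CPM in the others.

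Of 22 hypoxia genes 15 were higher and 1 lower in CF cells in normal glucose (17 and 1 adjusted over the list alone, camera adjusted p = 2.86e-05, adjusted p = 0.386 with an estimated correlation). ERO1A, the oxidase of disulfide bond formation, was 1.89-fold higher, at 3011 ± 113 against 1590 ± 143 CPM (n = 6 each), and the angiogenic factor VEGFA was 1.66-fold higher. The mitophagy receptor BNIP3L, which lies in a block of chromosome 8 described below that is lower in CF cells, was lower (log2 -0.64). In high glucose 8 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.235). Of 28 glycolysis and glucose transport genes 12 were higher in normal glucose (12 adjusted over the list alone, camera adjusted p = 0.00336, adjusted p = 0.39 with an estimated correlation). In high glucose 7 were (8 adjusted over the list alone, adjusted p = 0.0168, adjusted p = 0.62 with an estimated correlation). Examples were ALDOC at 1.98-fold and GAPDH at 1.35-fold in normal glucose. Of 35 unfolded protein response and ATF4 genes 15 were higher, such as the chaperone HSP90B1 (log2 0.56) and the disulfide isomerase PDIA4 (log2 1.01), and 5 lower (17 and 6 adjusted over the list alone, adjusted p = 0.000832, adjusted p = 0.386 with an estimated correlation). The members that were lower were ASNS, PSAT1 and PHGDH of amino acid synthesis, CHAC1 of glutathione breakdown and the ubiquitin ligase SYVN1, of which SYVN1 and PHGDH, like PDIA4, lie in such blocks.

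Of 9 gap junction genes 5 were higher in CF cells in normal glucose (5 adjusted over the list alone, camera adjusted p = 0.000832, adjusted p = 0.386 with an estimated correlation), including the connexin GJB2 (1.95-fold), the channel gene PANX1 (1.79-fold, where blocks of chromosome 11 overlap) and GJB5 (1.72-fold). Of 34 interferon response genes 14 were higher and 2 lower (15 and 3 adjusted over the list alone, adjusted p = 0.00644, adjusted p = 0.706 with an estimated correlation), with the RNA sensor OAS2 at log2 1.04. The basal cell list had 5 of 12 higher and 1 lower (5 and 2 adjusted over the list alone, adjusted p = 0.039, adjusted p = 0.424 with an estimated correlation). The keratins KRT6A (log2 1.24), KRT17 (log2 0.85) and KRT5 (log2 0.72) were higher and KRT14 lower. The call of the list was lost without CF normal glucose 4, 5 or 6 or WT normal glucose 2, 4, 5 or 6 (adjusted p from 0.0536 to 0.0736). The secretory cell list had 3 of 6 higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.0222, adjusted p = 0.39 with an estimated correlation), with the antiprotease SLPI (log2 1.07) higher. The pentose phosphate and NRF2 list was lower, with 10 of 25 lower and 1 higher (11 and 1 adjusted over the list alone, adjusted p = 0.00471, adjusted p = 0.386 with an estimated correlation). Examples were the cystine transporter SLC7A11 (log2 -1.46) and NQO1 (log2 -0.58), and 1 member, GSR, lies in a block. The cholesterol synthesis list was lower too, with 9 of 25 lower and 1 higher (10 and 1 adjusted over the list alone, adjusted p = 0.000832, adjusted p = 0.73 with an estimated correlation), as in FDFT1 (log2 -1.03) and STARD4 (log2 -0.51). The members FDFT1, TM7SF2, DHCR7 and INSIG1 lie in blocks. None of the 9 list calls in normal glucose held with an estimated correlation.

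Among 31 tight junction genes 4 were higher and 4 lower in CF cells in normal glucose (5 and 4 adjusted over the list alone, camera adjusted p = 0.852), with the claudins CLDN23 (log2 -1.39, in the chromosome 8 block) and CLDN3 (log2 -0.84) lower. Of 26 adherens junction and desmosome genes 7 were higher and 3 lower (8 and 3 adjusted over the list alone, adjusted p = 0.304), with CDH3 (log2 0.55) higher and NECTIN1 (log2 -0.72) lower. E-cadherin, CDH1, was 1.22-fold higher (adjusted p = 0.00379). OCLN (log2 0.13, adjusted p = 0.0513), TJP1 (log2 -0.20), CLDN4 (log2 0.10), TXNIP (log2 -0.21) and CFTR (log2 0.12, adjusted p = 0.206) did not pass. CFTR was called higher in CF cells in libraries numbered 1 to 3 alone (log2 0.21) and not called in those numbered 4 to 6 alone (log2 0.03). Of 27 ion and fluid transport genes 7 were higher and 6 lower (7 and 6 adjusted over the list alone, adjusted p = 0.687), with SCNN1A at log2 0.38 and SLC4A2, in a block of chromosome 7, at 1.31-fold. The cytokine and NF-kB list had 9 of 32 higher and 2 lower (9 and 3 adjusted over the list alone, adjusted p = 0.304), the chemokine CCL2 being lower (log2 -2.84). Of 20 glucose-responsive genes 3 were higher and 7 lower (4 and 7 adjusted over the list alone, adjusted p = 0.785).

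In high glucose 7 lists were called between the lines with the preset correlation and none with an estimated correlation, where their adjusted p ran from 0.549 to 0.778. They were gap junction (4 of 9 higher, 6 adjusted over the list alone, adjusted p = 0.0126), cholesterol synthesis (7 of 25 lower, 1 higher; 7 and 1 adjusted over the list alone; 0.0126) and glycolysis and glucose transport. Others were NRF2 (10 of 25 lower, 3 higher; 10 and 3 adjusted over the list alone; 0.0168), the unfolded protein response (12 of 35 higher, 1 lower; 12 and 4 adjusted over the list alone; 0.0168), secretory cell (3 of 6 higher, 1 lower; 3 and 1 adjusted over the list alone; 0.0204) and actin and myosin. In the actin and myosin list 11 of 29 were lower and 2 higher (11 and 2 adjusted over the list alone, adjusted p = 0.017), with the myosin kinase MYLK (log2 -0.84) and the light chain MYL9 (log2 -0.48) lower. Its members MYL12A, MYL12B, ROCK1, CFL1 and ZYX lie in blocks. CDH1 (log2 0.26), CLDN4 (log2 0.21), VEGFA (log2 0.37) and TXNIP (log2 0.50) were called higher in CF cells in high glucose. TXNIP lies in a block of chromosome 1 that is lower in CF cells, so it went against its block. VEGFA was not called without WT high glucose 3 (adjusted p = 0.0533), CDH1 without WT high glucose 1 (0.0504), and TXNIP without CF high glucose 5 (0.0527) or WT high glucose 4 (0.0503), without a low-count filter (0.0918) or on FPKM without a filter (0.063). CLDN4 was not called without CF high glucose 1 to 5 or WT high glucose 3, 4 or 5 (0.0582 to 0.147) or on FPKM without a filter (0.0682). The secretory cell list was not called without WT high glucose 4 (0.0537) or 5 (0.067).

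In all, 3979 of 16338 genes were called in normal glucose (1862 higher and 2117 lower in CF; 774 by at least 2-fold) and 3253 in high glucose (1528 and 1725; 682 by at least 2-fold). Both comparisons called 2441 genes, of which 1124 were higher, 1310 lower and 7 opposite, against 174 and 224 by chance. The fold changes at the 2 glucose levels had r = 0.879 across genes, 0.817 in libraries numbered 1 to 3 and 0.765 in those numbered 4 to 6. A batch term gave 5637 and 4973 genes, libraries numbered 1 to 3 alone 3650 and 3034, and those numbered 4 to 6 alone 5111 and 4702. In libraries numbered 1 to 3 alone the gap junction (adjusted p = 0.0882), glycolysis (0.0882) and basal cell lists (0.199) in normal glucose and the actin and myosin list (0.126) and CLDN4 (0.163) in high glucose were not called. In those numbered 4 to 6 alone the unfolded protein response list in high glucose was not (0.383).

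Genes that differed between the lines lay partly in blocks. In a scan of 1529 overlapping windows of 50 neighbouring genes, 60 had a median log2 fold change of at least 0.3 in size, and beyond the largest of 200 shuffled orders, at both glucose levels, and they formed 7 regions on GRCh38. CF cells had lower levels over chromosome 8 from 0.213 to 56.1 Mb (median 0.537-fold, 175 of 220 genes called lower), chromosome 18 from 0.0474 to 24.2 Mb (0.731-fold), chromosome 11 from 63.6 to 66.6 Mb (0.765-fold) and from 68.1 to 94.2 Mb (0.778-fold), and chromosome 1 from 120 to 147 Mb (0.796-fold). They had higher levels over chromosome 7 from 129 to 157 Mb (1.47-fold, 119 of 190 genes called higher) and chromosome 11 from 85.7 to 103 Mb (1.21-fold). The last 2 regions of chromosome 11 overlap from 85.7 to 94.2 Mb, since windows of 50 genes span the place where the direction turns, so the direction there is not set by the scan. The regions hold 5.21% of the genes scanned and 578 of 3968 called genes (14.6%). FDFT1, BNIP3L, CLDN23 and TCIM lie in the chromosome 8 region, SLC4A2 in that of chromosome 7, PANX1 where those of chromosome 11 overlap and TXNIP in that of chromosome 1. CFTR lies outside them.

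**Figure D5:**
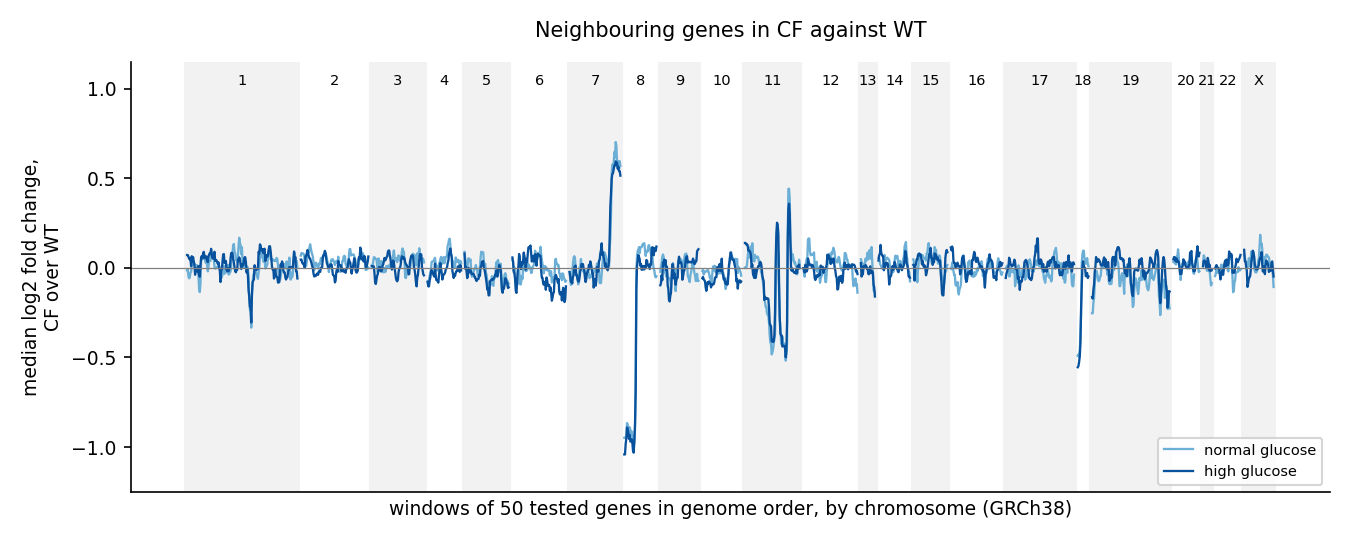
Median log2 fold change (CF over WT) of windows of 50 tested genes in genome order, by chromosome, in normal and high glucose; the x axis counts genes, not bases. The windows of the start of chromosome 8 lie near -1 and those of the end of chromosome 7 above 0.5 at both glucose levels.

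The last comparison set WT cells in normal glucose against WT cells labelled not polarized, also in normal glucose. The labels call these cells not polarized but give them the same Transwell plating and treatment text as the others, so how they were grown is not settled, and format, density and time cannot be told apart here. In the polarized cells, the oxygen sensor EGLN3 was 34.2-fold higher (30.4 ± 3.32 CPM, n = 6, against 0.88 ± 0.18 CPM, n = 3; ENSG00000129521, chromosome 14, 33924231 to 34462774) and ANGPTL4, an inhibitor of lipoprotein lipase, 28.2-fold higher. The peptide gene EDN2 was 74.1-fold, VIT 50.3-fold and the natriuretic peptide receptor NPR1 36.2-fold higher, and TXNIP was 15.6-fold higher. The immediate early genes FOS (log2 -5.38) and FOSB (log2 -5.31) were lower, as were DOCK4 (log2 -3.24), SERPINE2 (log2 -3.06) and ANKRD1 (log2 -3.01).

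Of 21 hypoxia genes 18 were higher and 2 lower (18 and 2 adjusted over the list alone, camera adjusted p = 5.7e-29), such as NDRG1 (6.98-fold) and ERO1A (5.53-fold). In turn 24 of 28 glycolysis and glucose transport genes were higher and 2 lower (24 and 2 adjusted over the list alone, adjusted p = 1.25e-15), such as SLC2A3 (10.5-fold) and PDK1 (3.02-fold). Of 27 extracellular matrix and mesenchymal genes 20 were higher and 3 lower (20 and 3 adjusted over the list alone, adjusted p = 2.06e-09): the collagen crosslinker LOXL2 was 7.77-fold and fibronectin FN1 6.21-fold higher, while the transcription factors SNAI1 and SNAI2 were lower. Of 32 cytokine and NF-kB genes 20 were higher and 6 lower (20 and 6 adjusted over the list alone, adjusted p = 8.62e-07), with CCL5 at 4.51-fold and the adhesion receptor ICAM1 at 3.79-fold. The pentose phosphate and NRF2 list was lower, with 15 of 23 lower and 2 higher (15 and 3 adjusted over the list alone, adjusted p = 3.69e-05). These 5 calls held with an estimated correlation, at adjusted p = 0.0143, 0.0135, 0.0121, 0.0135 and 0.0197.

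Of 24 hemidesmosome and basement membrane genes 18 were higher and 2 lower (18 and 2 adjusted over the list alone, adjusted p = 5.88e-09; adjusted p = 0.0671 with an estimated correlation), with the hemidesmosome collagen COL17A1 at 4.89-fold, the integrin ITGB4 at 2.75-fold and COL4A2 at 2.09-fold. Of 9 gap junction genes 7 were higher (8 adjusted over the list alone, adjusted p = 0.000382; adjusted p = 0.2 with an estimated correlation). Tight junction genes went both ways, 9 of 31 higher and 9 lower (9 each adjusted over the list alone, adjusted p = 0.869), with CLDN1 at 1.82-fold, CXADR at 1.48-fold, OCLN at log2 -0.18 and TJP1 at log2 -0.37. Of 25 adherens junction and desmosome genes 12 were higher and 7 lower (12 and 7 adjusted over the list alone, adjusted p = 0.106), with CDH3 at 1.84-fold, NECTIN2 at 1.65-fold and CDH1 at log2 0.38. In the ion and fluid transport list 5 of 27 were higher and 8 lower (5 and 8 adjusted over the list alone, adjusted p = 0.23), the water channel AQP3 (0.249-fold) and the chloride channel ANO1 (log2 -0.90) being lower. CFTR (log2 0.03, adjusted p = 0.666) and CLDN4 (log2 -0.17, adjusted p = 0.115) did not pass, and OCLN was not called without not polarized 1 (adjusted p = 0.0875).

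Further lists were called with the preset but not with the estimated correlation. Higher in the polarized cells were glucose-responsive (9 of 21 higher, 5 lower; 10 and 5 adjusted over the list alone, adjusted p = 0.00544), among them PFKFB4 at 3.96-fold, and antigen presentation (10 of 19 higher, 10 adjusted over the list alone; 0.000382). So were innate defence (8 of 17 higher, 1 lower; 8 and 1 adjusted over the list alone; 0.0153), and cholesterol synthesis (15 of 25 higher, 3 lower; 16 and 3 adjusted over the list alone; 0.0486). The others were basal cell (5 of 11 higher, 1 lower; 5 and 1 adjusted over the list alone; 0.00544), ciliated cell (10 of 17 higher, 3 lower; 10 and 3 adjusted over the list alone; 0.0411) and ionocyte and neuroendocrine (6 of 8 higher, 6 adjusted over the list alone; 0.0119). The ciliated list's master regulator FOXJ1 was lower (log2 -1.77) while the axonemal gene DNAH5 was higher (log2 1.52). Lower were unfolded protein response and ATF4 (17 of 35 lower, 6 higher; 18 and 7 adjusted over the list alone; 6.59e-05), and cytosolic heat shock (9 of 18 lower, 1 higher; 10 and 1 adjusted over the list alone; 0.00136). So were squamous (8 of 16 lower, 2 higher; 8 and 3 adjusted over the list alone; 0.0153) and simple epithelial and polarity (11 of 27 lower, 3 higher; 11 and 3 adjusted over the list alone; 0.00544). With an estimated correlation the adjusted p was 0.0671 for innate defence, basal cell, ionocyte, unfolded protein response, squamous and simple epithelial, 0.198 for antigen presentation, 0.2 for ciliated cell, 0.217 for glucose-responsive and heat shock, and 0.573 for cholesterol synthesis. The ciliated list was not called without not polarized 2 (adjusted p = 0.0674), nor cholesterol synthesis without WT normal glucose 1, 3 or 6 or not polarized 1, 2 or 3 (0.0528 to 0.0797) or with RLE factors (0.0512). The ciliated list was not called with a block for the library number either (0.0729).

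In all, 8045 of 16105 genes were called (4188 higher and 3857 lower in the polarized cells). Of these, 1947 differed by at least 2-fold, 1419 higher and 528 lower. With polarized libraries numbered 1 to 3 alone the count was 8984, and with those numbered 4 to 6 alone it was 9150. The ciliated list was not called in either set (adjusted p = 0.0872 and 0.0702), and cholesterol synthesis not in numbers 4 to 6 (0.0808). The share of counts on mitochondrially encoded genes was 1.74 ± 0.00907% (SD, n = 3) in the not polarized and 2.87 ± 0.429% (n = 6) in the polarized cells. That on ribosomal protein genes was 4.58 ± 0.102% and 3.3 ± 0.56%, and that on the 10 most abundant genes 3.37 ± 0.00265% and 6.17 ± 0.239%. No test was run for these shares.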

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

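The tests of depth, mitochondrial share, and transcript length and GC content for the library numbers, the batch term and the CF fit without a library were chosen after the result they concern was seen. A library was noted when its gap to the nearest other library of its group was large for the group's range, which chance gives in about 1 of 20 groups. By this measure 20 of 436 gene groups (4.59%) and 1 of 20 groups of library measures were noted, so their number is what chance gives.

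In WT normal glucose, library 2 was highest for NOG (gap over range 0.646), MAN1A1 (0.675) and ANGPTL4 (0.693), library 3 for HSPA1B (0.714), and library 4 was highest for DDX58 (0.692) and lowest for NECTIN2 (0.652). In WT high glucose, library 2 was highest for NOG (0.827), SLC2A1 (0.716) and EDN2 (0.831), and library 1 for MAN1A1 (0.813). In CF normal glucose, library 4 was highest for SLC4A2 (0.647) and lowest for SCNN1A (0.703), library 1 was highest for PPP2R2B (0.646) and library 5 for ANO1 (0.753). In CF high glucose, library 4 was lowest for CYP24A1 (0.696) and highest for SGK1 (0.658), library 1 was highest for OCLN (0.637), library 6 lowest for MMP15 (0.691), library 3 highest for ERO1A (0.718) and library 2 lowest for SERPINE2 (0.628). CF high glucose 2 also had the lowest share of counts in its 10 most abundant genes (5.65% against a mean of 6.11% in the others; 0.668).

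The response to glucose differed between the lines, by the test of the difference, for CTGF (-0.63), HDAC9 (-0.59), FHL2 (-0.55), PLIN2 (-0.79), APCDD1 (0.47) and MMP15 (0.37), and for the hypoxia (adjusted p = 1.35e-10), cytokine and NF-kB (7.01e-10) and wound healing and protease lists (4.99e-06), though each of these lists had an adjusted p = 0.124 with an estimated correlation. Of 100 splits, 3 with the real one included called as many genes (real value 6, highest other 1147). With the batch term, 3 of 100 splits made within the library numbers did (real value 146, highest other 479). Of the other splits, 96 and 95 called 0 genes, while the highest called several times the real number. Moving the glucose labels within a line also removes the response that the lines share. The splits therefore do not show what chance gives for the difference alone, and chance is not excluded.

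Libraries numbered 1 to 3 stood apart from those numbered 4 to 6 in each of the 4 groups, with 8109 genes called between them over 23 libraries. Depth does not account for it, since the libraries numbered 4 to 6 had the higher mean total in only 2 of 4 groups, nor does the mitochondrial share, which overlapped between the sets in 2 of 4. Length and GC content held 11.8% of the variance of the difference in CF and 13.6% in WT cells and cannot be told apart from a difference in library preparation or culture, as the labels give no batch. The difference in CF cells correlated across genes, which are not independent, with the difference between polarized and not polarized WT cells (r = 0.3, at the limit set for this test, and 0.308 with length and GC removed). A difference in the degree of polarization between the sets is a candidate explanation for a part of it that stays open beside an unlabelled batch. Lists called for polarization did not all move with it in numbers 4 to 6 over 1 to 3. The 2 median log2 values were 0.508 and 0.255 for hemidesmosome, 0.617 and 0.134 for extracellular matrix and 1.42 and 0.0173 for hypoxia. They were 0.715 and -0.000742 for glycolysis, 0.686 and -0.0711 for antigen presentation and 0.341 and -0.25 for cholesterol synthesis. Hypoxia, glycolysis, antigen presentation and cholesterol synthesis argue against it as the whole difference. Of the other lists higher in polarized cells, glucose-responsive (0.139), ciliated (0.108), basal (0.0707), cytokine (0.0536), ionocyte (0.0351) and innate defence (0.0214) were higher. Gap junction (-0.0484) was lower. Of those lower in polarized cells, NRF2 (-0.0685), heat shock (-0.0555), squamous (-0.0424) and unfolded protein response (-0.0423) were lower. Simple epithelial (0.018) was higher.

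More genes were called for glucose in CF than in WT cells. The smaller number of WT libraries does not explain it, as CF cells without high glucose library 6 still had 1166 calls. Nor does a larger spread in WT, since the groups shared an estimate of the spread in the fit. With the difference between the sets of library numbers removed, the median residual SD over genes in WT was 0.955 of that in CF. A larger response in CF cells may contribute and stays open. The slope of CF against WT fold changes, by total least squares through the origin, was 1.07 (95% interval 0.993 to 1.17). It covers the 254 genes called in both lines and leaves out those called in CF alone, so it does not decide. The interval came from resampling these genes, which are not independent, and not the libraries. The change was larger in size in CF cells for 132 of the 254 (52%). For the WT count 2 of 100 splits were as large (real value 482, highest other 3972), and for the CF count 2 of 100 (1374 and 5310); in both, the highest other was the split of numbers 1 to 3 against 4 to 6. Within the library numbers and with the batch term, only the real split of 100 was as large in WT (real value 1418, highest other 1219) and in CF (2811 and 868). This makes chance unlikely, but 100 of 200 possible splits were drawn and in WT another came close, so chance is not excluded.

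CF and WT cells differed in blocks of neighbouring genes, with 60 windows of 50 genes at a median log2 of at least 0.3 in size and beyond the largest of 200 shuffles at both glucose levels. A copy number difference between the clones is consistent with these blocks and remains a hypothesis, since RNA alone was measured. Outside the 7 regions 3390 genes were called, so a copy number difference in these regions leaves most calls open. The scan could miss shorter blocks or smaller shifts, so the calls outside are not shown to be free of such differences. The counts between the lines exceeded all other splits, at 1 of 100 in normal glucose (real value 3979, highest other 3137, the split by library number) and 1 of 100 in high glucose (3253 and 2129), as did the polarized count (1 of 84 splits, 8045 and 1046).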

How the results depend on the processing

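The batch term, the sets of library numbers alone and the CF fit without a library were chosen after the result was seen. Counts of called genes kept within 1.5 times of the reported ones except as follows. For glucose in WT (482), DESeq2 gave 809, no low-count filter 319, FPKM without a filter 312, a surrogate variable 1484, the batch term 1418 and numbers 4 to 6 alone 823. For glucose in CF (1374), no filter gave 891, the surrogate variable 2733, the batch term 2811 and numbers 4 to 6 alone 2328. For the interaction (6), DESeq2 gave 67, the surrogate variable 137, FPKM without a filter 3, the batch term 146, numbers 1 to 3 alone 1 and numbers 4 to 6 alone 387. For the lines in high glucose (3253), the batch term gave 4973. The overlap of glucose calls (254) was 418 with DESeq2, 156 without a filter, 165 on FPKM without a filter, 757 with the surrogate variable, 752 with the batch term and 411 in numbers 4 to 6 alone. No filter adjusts over more genes; the cause of the others was not tested. A block for the library number gave 1541 (WT), 3360 (CF), 205 (interaction), 5007 and 4018 (lines in normal and high glucose), 8885 (polarized) and overlaps of 916 and 2995, though the numbers did not pair the samples. With a library left out the counts ran from 281 to 465 in WT, 1065 to 1597 in CF, 0 to 19 for the interaction, 3629 to 4023 and 2856 to 3122 for the lines and 6666 to 8406 for polarized cells. Of 162 called values of named genes, 0 reversed under any alternative; 144 held their call with each library left out, 147 in numbers 1 to 3 alone, 158 in numbers 4 to 6 alone, 152 on FPKM without a filter and 154 without a low-count filter. Of 157 values 154 held it on FPKM plus 1 and plus 0.1, and of 156 values 153 in fits with another set of libraries. The actin and myosin list for glucose in CF reversed in numbers 1 to 3 alone (camera p signed by direction 0.647, adjusted p = 0.844), and the cause was not tested. With the batch term and an estimated correlation, 0 of 9 list calls held for glucose in WT, 2 of 7 in CF and 0 of 3 for the interaction. Between the lines 0 of 9 held in normal and 0 of 7 in high glucose. Fits of the 2 compared groups alone could not be had for the interaction, nor a batch term for the polarized comparison, whose not polarized libraries have no numbers 4 to 6. Calls are limited by depth and by the number of libraries, and a gene not called is not shown to be unchanged.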

Other observations

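The test of whether 2 lists account for the opposite change described last was chosen before its result was seen, and the relation itself after. Lists of other cell types had few tested members and few calls in high glucose. Of 13 fibroblast genes 5 were tested, of 12 endothelial genes 4, of 20 immune genes 3 and of 16 alveolar genes 8, and none was called for glucose in either line (adjusted over the list alone, 1 fibroblast gene was lower in WT and 1 immune gene higher in CF cells). Antigen presentation had 0 calls of 19 in WT and 1 lower in CF cells, oxidative phosphorylation 0 of 33 in both, ciliated cell 1 of 17 lower in both (RFX3), squamous 1 of 14 higher in WT (TGM1), secretory cell 0 of 6 in both and ionocyte 1 of 9 higher in CF (FOXI1). In the apoptosis and p53 list, the cell cycle inhibitor CDKN1A fell in both lines (log2 -0.24 in WT and -0.48 in CF) and MDM2 fell in CF (log2 -0.44), with 1 of 24 higher and 1 lower in WT and 2 and 3 in CF (adjusted over the list alone 2 and 1, and 2 and 3).

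The libraries numbered 4 to 6 had lower oxidative phosphorylation (27 of 33 lower, 3 higher), higher hemidesmosome and basement membrane (20 of 24 higher, 3 lower) and lower cholesterol synthesis transcripts (19 of 25 lower, 0 higher) than those numbered 1 to 3, with adjusted p = 0.253, 0.253 and 0.429 with an estimated correlation. In the hypoxia list 5 of 22 were higher and 7 lower, without a shared direction (camera adjusted p = 0.839).

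Genes that changed between not polarized and polarized WT cells tended to change the other way in high glucose in CF cells. Across 15877 genes, which are not independent, r was -0.176, with -0.182 with the batch term, -0.182 in libraries numbered 1 to 3 and -0.0875 in those numbered 4 to 6, and 516 of 859 genes called in both comparisons (60.1%) went opposite ways. Without the 47 members of the hypoxia and glycolysis lists r was -0.169, and among those members it was -0.467. So few genes could hardly move r over 15877 genes, so this test cannot decide on a wider hypoxia or glycolysis response. Length and GC content do not account for the relation (r = -0.183 with them removed). That high glucose may lower part of the program that is higher in polarized cells remains a hypothesis, found and tested on the same data.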
